A study of Vibrio parahaemolyticus RIMD 2210633 with 16 samples.

How the data were processed

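Total RNA of Vibrio parahaemolyticus, grown in alkaline peptone water at 37 °C, was measured on 1-colour Agilent expression arrays after Cy3 labelling. Cultures grown for 4 h made the exponential group and cultures grown for 7 h made the early stationary group, with 8 arrays in each group that the labels call biological replicates. Exponential phase was the reference, so every log2 difference is early stationary minus exponential.

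The deposited scanner files hold signal intensity, made by the authors with Agilent Feature Extraction 10.5.1.1 per the file headers. The processed signal in them is an intensity that the software had subtracted for background and detrended within the array, with a small positive value put in for spots not above background; per the file headers it was not scaled between arrays. The deposited series table holds log2 values. A comparison with the scanner files showed the same rank order of probes on every array and nearly identical sorted values across the 16 columns, as quantile normalization between arrays leaves them. The software that made that table is not given in the sources used here. The files also carry quality marks per spot, set by the scanner software per the file headers and in no unit. They were used to leave out 37 spots marked as outliers and to decide which genes were measured; 0 spots were saturated. No pair of arrays held identical values.

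The array carries 15199 gene probes, with a median of 3 probes per gene, for 4820 genes. The main values were the log2 processed signal minus the 75th percentile of the gene probes of the same array, and a gene's value was the median of its probes. A gene was tested if at least 1 of its probes was well above background on at least 4 of the 16 arrays, which left 4102 genes, 2753 of them on chromosome 1 and 1349 on chromosome 2. Product names, locus tags, chromosomes and positions are those in the deposited array annotation. The genome build is not given in the sources used here. The annotation has no gene symbols, so 193 genes were matched to the symbols of the lists by their product text, after the annotation had been seen and before any value had been looked at.

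Differences were tested two-sided in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, growth phase as the only term) and data.table (version 1.17.8). P-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene is said to have risen or fallen if its adjusted p was under 0.05, and a second count also asks for a difference of at least 2-fold. For each array 3 values were computed, which were compared in a two-sided exact permutation test over all 12870 ways of dividing 16 arrays into 8 and 8. The smallest p that this test can give is 0.00016, and the p-values were adjusted over the 3 tests. The values were the mean of chromosome 2 genes minus that of chromosome 1 genes, and for each chromosome the least-squares slope of the log2 value on the distance from the replication origin. That distance is 0 at the first locus of the chromosome and 1 at the opposite point of the circle. The number of arrays limits the precision of every value. Data were simulated with 50 changed genes of each size among 4102, with independent arrays, no slide effect and no correlation between genes. There limma recovered 8% of changes of 0.5, 44% of changes of 1, 78% of changes of 1.5 and 96% of changes of 2 on the log2 scale. Of its 118 calls 5 were false. The real arrays clustered by slide, so these shares may not hold for them.

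Before the data were examined, 34 gene lists were fixed by locus range, product text or symbol, together with a set of single genes and the main tests and alternatives. From the lists 10 members were left out because their product contradicts the list's name. The 32 lists with at least 4 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists; camera with an estimated correlation and limma's fry were alternatives. The gene fixed as csrA was dropped because the annotation gives its locus another product, which left 18 single genes.

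Genes are named by a rule fixed beforehand. Its first part takes the 10 largest rises and the 10 largest falls among genes whose groups do not overlap and that were well above background on all 8 arrays of the higher group, leaving out hypothetical proteins except the one with the largest change each way. Its second part takes the fixed genes. Its last part takes up to 4 members of each described list that passed, by the size of the change (or, where none passed, the member with the smallest p). The 15 lists described with their members were chosen after the results were seen. A gene said to be named for another reason was chosen after its values were seen. Where a gene was well above background on no array of a group, its change is given as a bound computed against the background, or with no fold.

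The arrays lie on 3 slides, each scanned on 1 date, and each slide holds arrays of both growth phases. Slide 1 holds exponential replicates 1, 2 and 3 and early stationary replicates 1, 2 and 3. Slide 2 holds exponential replicates 4 and 5 and early stationary replicates 4, 5 and 6. Slide 3 holds exponential replicates 6, 7 and 8 and early stationary replicates 7 and 8. The values were therefore also computed with slide as a block and within each slide. The other alternatives were quantile normalization, scaling to the array's median or to the mean of 6 spike-in control probes, normexp background correction with an offset of 50, no filter or a strict filter on dim genes, the brightest probe per gene, the values of the series table, the replicate number as a block, leaving out a slide, and eBayes with a trend. Slide means as replicates (with slide as a block for genes and lists, and without it for values per array), the removal of exponential arrays with unusual signal, and a set test with slide as a block and an estimated correlation were added after the data had been seen. No array was left out of the main values.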

Results

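The expression of V. parahaemolyticus genes was measured on 16 arrays, 8 from exponential cultures and 8 from early stationary cultures, spread over 3 slides. The 75th percentile of the processed signal ranged from 24.9 to 212 on the exponential arrays and from 52.6 to 81.6 on the early stationary arrays. Of 15199 probes, 6778 to 14439 were well above background on the exponential arrays and 7633 to 10185 on the early stationary arrays. The widest departures were exponential replicate 2, with 14439 probes well above background, exponential replicate 6, with the lowest signal, and exponential replicate 8, whose negative controls had the highest mean signal of 51. The first principal component held 41.7% of the variance, but it did not separate the arrays by growth phase alone. The exponential arrays of slide 1 lay at -8.5, 0.5 and -8.8 on it. That is nearer to the early stationary arrays (-30.1 to -23.2) than to the other exponential arrays (42.4 to 51.2). Spearman correlations were 0.76 to 0.99 among exponential arrays, 0.91 to 0.98 among early stationary arrays and 0.76 to 0.94 between phases. Within a growth phase the arrays clustered by slide: the share of a gene's squared deviations that lay between slides was 71.8% among exponential and 77.6% among early stationary arrays for the median gene, against 28.6% if slides did not matter. The labels call the arrays biological replicates, but arrays of 1 slide were more alike than arrays of different slides, so the p-values below treat as independent arrays that were not fully so.

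With the main scaling, early stationary cultures had higher transcript levels of the capsular polysaccharide genes, of several genes annotated with acyl-CoA substrates and of part of the type III secretion system 2 region. Lower levels were found for many genes of the polar flagellum and the chemoreceptors and for some genes of sugar uptake and nucleotide synthesis. The gene of the stationary phase sigma factor RpoS rose, and the genes of the quorum sensing regulators OpaR, AphA and LuxO did not pass the threshold with the main scaling. Several of these differences depended on scaling or slide. The median of type III secretion system 2 was -0.62 with the spike-in controls, where the RpoS gene was not called. That of the chemoreceptors was 0.1 with normexp, and that of nucleotide synthesis was 0.17 on slide 1.

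The main comparison asked which genes differ between early stationary and exponential phase. Of 4102 tested genes, 1324 (32.3%) passed an adjusted p of 0.05 in limma, 505 of them higher and 819 lower in early stationary phase. At least 2-fold differences were found for 780 of them, 358 higher and 422 lower. On all 3 slides 1189 of the 1324 genes, and 713 (91.4%) of the 780 genes, differed in the same direction. The genes were called on these same arrays, so such agreement among slides, here and below, is partly built in. With slide as a block 1771 genes passed, 691 higher and 1080 lower. With the mean of each slide and phase taken as 1 replicate and slide as a block, 239 genes passed, 162 higher and 77 lower, and all 239 were among the 1324; for single genes, slide means below are always fitted with this block. In 86 (6.5%) of the called genes the probes of the gene disagreed in direction. The calls took 32.1% of the 2753 tested genes of chromosome 1 and 32.6% of the 1349 of chromosome 2, but the directions differed. At 2-fold 185 genes of chromosome 1 and 173 of chromosome 2 were higher, and 308 and 114 were lower. Of 1403 tested genes with hypothetical products, 402 were called.

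The split between higher and lower calls depended on the scaling. The share of higher calls was 38.1% with each array's 75th percentile, 54% with its median, 3.37% with its spike-in controls (99 higher, 2841 lower) and 69.0% after normexp background correction (557 higher, 250 lower). The median log2 difference of all tested genes was -0.15 with the main scaling, -0.07 after quantile normalization, 0.01 with the array median, -1.32 with the spike-in controls, 0.21 with normexp and -0.07 in the series table. At 2-fold the majority also turned: it was lower with the main scaling, but 400 genes were higher and 330 lower after quantile normalization, 471 and 289 with the array median, 112 and 61 with normexp, 370 and 296 in the series table and 402 and 358 with the brightest probe. With the spike-in controls 96 were higher and 2650 lower. Normexp adds its offset of 50 to the corrected signal before the log2 is taken. The median processed signal was 6.97 to 71 on exponential and 12.1 to 19.7 on early stationary arrays. The offset therefore shrinks the log2 differences of dim genes and shifts them by an amount that depends on the array's signal. For such genes normexp values below reflect the offset as well as the background correction. All changes given here are relative to the main scaling.

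The 10 largest rises had adjusted p from 2.7e-08 to 0.00022. The naming rule itself asks for signal well above background on all 8 early stationary arrays and for groups without overlap. A rise on all 3 slides follows from that rule and is not a separate result. VPA1123, annotated as an acyl-CoA thiolase (chromosome 2, 1186125 to 1187303), rose from -1.0 ± 0.91 to 3.93 ± 1.79 (SD, n = 8 per group, log2 relative to the array's 75th percentile), which is 30.5-fold. VPA0647 (chromosome 2, 651901 to 652995) and VPA0646 (650925 to 651908), both annotated as components of pyruvate dehydrogenase E1, rose 27.4-fold and 21.2-fold. VPA0647 reached 9.21 ± 0.34 in early stationary phase from 4.43 ± 2.17. The fimbrial protein gene VP2423 (chromosome 1, 2541397 to 2541570) rose from -3.41 ± 0.4 to 1.23 ± 0.83, which is 24.9-fold against an exponential level that was well above background on only 2 of 8 arrays. With normexp its log2 difference was 1.93 in place of 4.64. The agglutination protein gene VP1631 (chromosome 1, 1736087 to 1737445) rose 22.6-fold and the enoyl-CoA hydratase gene VPA0624 (chromosome 2, 629392 to 630528) rose 20.5-fold. The others were VP1315 for a multidrug resistance protein (18.3-fold), VP1911 for an extracellular solute-binding protein (17.3-fold), VP2607 for a cytochrome c oxidase subunit (16.6-fold) and VPA1581 for a membrane protein (13.8-fold, well above background on 3 of 8 exponential arrays). At least 1 probe of VP2607 was well above background on each exponential array. Its exponential value was still dim, at -4.23 ± 1.09, which is lower than that of VP2423. With normexp all 10 rises passed but were smaller, at 4.41 for VPA0647, 3.9 for VPA0646, 3.57 for VPA1123 and 3.33 for VP1631, and down to 1.37 for VPA1581 and 1.29 for VP2607. The size and order of the rises thus depend on the background correction and its offset. Among the 10 largest rises of any product 1 was a hypothetical protein, VPA0330 (chromosome 2, 324655 to 325659), which rose 17.4-fold.

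The 10 largest falls had adjusted p from 2.1e-09 to 0.0014. The maltodextrin phosphorylase gene VPA1620 (chromosome 2, 1721961 to 1724414) fell from 2.3 ± 2.46 to -1.47 ± 0.35, which is 13.6-fold, by -1.02 on slide 1 and by -5.42 and -5.5 on slides 2 and 3. The maltose-inducible porin gene VPA1644 (8.27-fold) and the pullulanase gene VPA1638 (5.76-fold, with the call lost under normexp at -0.37, adjusted p = 0.27) also fell. The threonine 3-dehydrogenase gene VPA1509 (chromosome 2, 1612798 to 1613829) was above background on all 8 exponential arrays and on 0 of 8 early stationary arrays, so it was at least 3.21-fold lower. Its neighbour VPA1510, for 2-amino-3-ketobutyrate coenzyme A ligase (1613995 to 1615188), fell 9.66-fold, from 5.43 ± 0.52 to 2.16 ± 0.79. The orotate phosphoribosyltransferase gene pyrE (VP0178, chromosome 1, 191665 to 192306) fell 11.9-fold, from 1.12 ± 1.46 to -2.45 ± 0.79, and was above background on 6 of 8 early stationary arrays. The other falls were VP1850 for an acetyltransferase of the superintegron (7.98-fold), VP1711 for a response regulator (6.68-fold, with the call lost under normexp at -0.07, adjusted p = 0.8), VP2166 for a lactoylglutathione lyase (5.79-fold) and VPA0805 for a glycine cleavage protein (5.58-fold). With normexp VPA1510 fell by 3.25, but VP1850 by 0.31 and VPA1509 by 0.43. The size of the falls to dim levels thus depends on the background correction and its offset. Among the 10 largest falls of any product 2 were hypothetical, of which VP2167 (chromosome 1, 2278997 to 2279281), next to VP2166, fell 6.26-fold. With slide means as replicates all 22 of these genes named by size passed. They had been picked for groups without overlap in the same data, so this is not independent support.

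**Figure D1:**
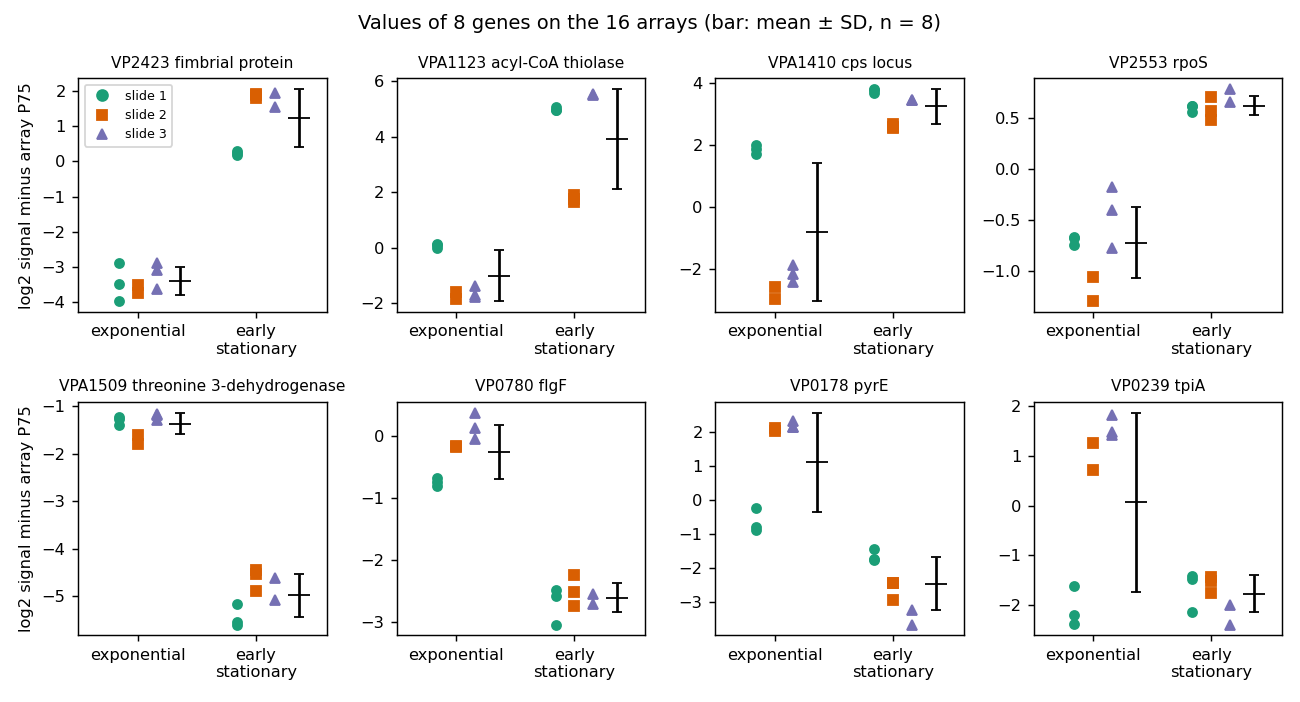
Log2 signal relative to the array's 75th percentile of 8 genes on each of the 16 arrays, by growth phase, with the slide as colour and shape and bars for the mean ± SD of 8 arrays. VP2423 lay between -3.98 and -2.88 on exponential arrays, below all early stationary arrays, while VP0239 was as low on the exponential arrays of slide 1 as on early stationary arrays.

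Of 34 lists of related genes, 32 had at least 4 tested members, and 7 of these passed an adjusted p of 0.05 in camera with its preset correlation, 4 upward and 3 downward. With slide as a block the same 7 passed. With the correlation between genes estimated from the data 0 of the 32 passed, where 1 list, the polar flagellum, had an unadjusted p under 0.05, and fry, which asks whether a list moves on balance, gave 13. Of these 13, 6 had also passed camera. The other 7 were aminoacyl-tRNA synthetases (downward, fry adjusted p = 0.00018), translation factors (downward, 0.0049), quorum sensing (downward, 0.018), the TCA cycle and glyoxylate shunt (downward, 0.027), stationary phase and starvation (upward, 0.036), phage f237 (upward, 0.037) and RNA polymerase core (upward, 0.048).

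All 14 tested genes of the list for capsular polysaccharide and CpsQ-MfpABC rose by at least 2-fold, with a median log2 difference of 2.37 (5.16-fold). All 14 also passed when adjusted over the list alone. The camera adjusted p was 3.7e-09, with adjusted p = 0.59 with an estimated correlation. The largest rises were those of VPA1410 (chromosome 2, 1483490 to 1484323) from -0.81 ± 2.23 to 3.23 ± 0.55 and its neighbour VPA1409 (1482239 to 1483471), by 4.04 and 3.72, followed by VPA1412 and VPA1407, by 3.16 and 2.97. The median rise was 1.35 on slide 1, 3.45 on slide 2 and 3.4 on slide 3. In a camera test of the list's interaction slide 1 differed from the others (adjusted p = 3.3e-05). For every list this interaction was tested only with the preset correlation of 0.01, not with an estimated one. It takes the arrays of a slide as independent and sets 1 slide against 2, so its p does not measure a spread among slides. All scalings kept the upward median, which was 0.83 with normexp and 1.2 with the spike-in controls.

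The type III secretion system 2 lies on the pathogenicity island VPaI-7 of chromosome 2 with both tdh genes. Of its 40 tested genes 12 rose, 0 fell and 28 did not pass, and 12 rose when adjusted over the list alone. The median difference was 0.55 (camera adjusted p = 1e-05; adjusted p = 0.59 with an estimated correlation). The largest rises were VPA1345 (1.58), VPA1339 for an EscC protein (1.57, chromosome 2, 1411351 to 1412814), VPA1354 for an EscU protein (1.46) and VPA1362 for an EspD protein (0.98). The slide medians were 0.11, 1.02 and 0.84, and the interaction of slide 1 had an adjusted p of 0.0033. Of the 28 tested genes of the island outside this system 11 rose, 1 fell and 16 did not pass, again the same counts when adjusted over the list alone (median 0.49; camera adjusted p = 0.0011; adjusted p = 0.73 with an estimated correlation). Its largest rises were the neighbouring hypothetical genes VPA1387, VPA1388 and VPA1389 (chromosome 2, 1456667 to 1460819), by 3.13, 2.97 and 2.55, and VPA1396, by 2.43. The median of this list was -0.26 on slide 1, against 1.06 and 0.91 on slides 2 and 3 (interaction adjusted p = 9.5e-05). With spike-in scaling the medians of both lists turned negative, at -0.62 and -0.68, and of the 4 secretion genes named VPA1345, VPA1339 and VPA1354 were not called and VPA1362 was -0.19.

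Of the fixed virulence genes, tdhA (VPA1314, chromosome 2, 1391960 to 1392529) rose by 1.04 (adjusted p = 0.026) and tdhS (VPA1378, 1450828 to 1451397) by 1.71 (adjusted p = 0.0085). Their slide differences were 0.63, 2.5 and 0.2 for tdhA and 0.44, 3.83 and 1.35 for tdhS. The exponential value of tdhS was dim, at -4.18 ± 1.32. These genes are near-identical copies, and whether their probes also bind the transcript of the other copy was not tested. With the brightest probe neither passed (adjusted p = 0.095 and 0.053), and with spike-in scaling the difference of tdhA was -0.14 and tdhS was not called (0.54, adjusted p = 0.29). The regulators vtrA (VPA1332, 0.8, adjusted p = 0.055) and vtrB (VPA1348, 0.72, adjusted p = 0.097, above background on 3 exponential and 1 early stationary arrays) did not pass, nor did toxR (VP0820, 0.37, adjusted p = 0.11), toxS (VP0819, -0.11) and tlh (VPA0226, -0.26). With the array median vtrA (0.96, adjusted p = 0.028), vtrB (0.88, adjusted p = 0.024) and toxR (0.53, adjusted p = 0.046) passed, and vtrB also passed with normexp (0.53, adjusted p = 0.034) and in the series table (1.17, adjusted p = 0.0028). With spike-in scaling, where most genes were lower, toxR (-0.81, adjusted p = 0.022), toxS (-1.28, adjusted p = 0.0012) and tlh (-1.43, adjusted p = 0.012) passed as lower. The vtrA gene passed with the brightest probe (0.91, adjusted p = 0.044). It also passed with slide as a block (0.74, adjusted p = 0.0078), and so did toxR (0.33, adjusted p = 0.021), but neither passed with slide means as replicates (adjusted p = 0.32 and 0.68). The gene exsA (VP1699) was not measured above background on enough arrays to be tested. Of 29 tested genes of the type III secretion system 1, 2 rose, 2 fell and 25 did not pass (2 and 0 when adjusted over the list alone; camera adjusted p = 0.45).

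**Figure D2:**
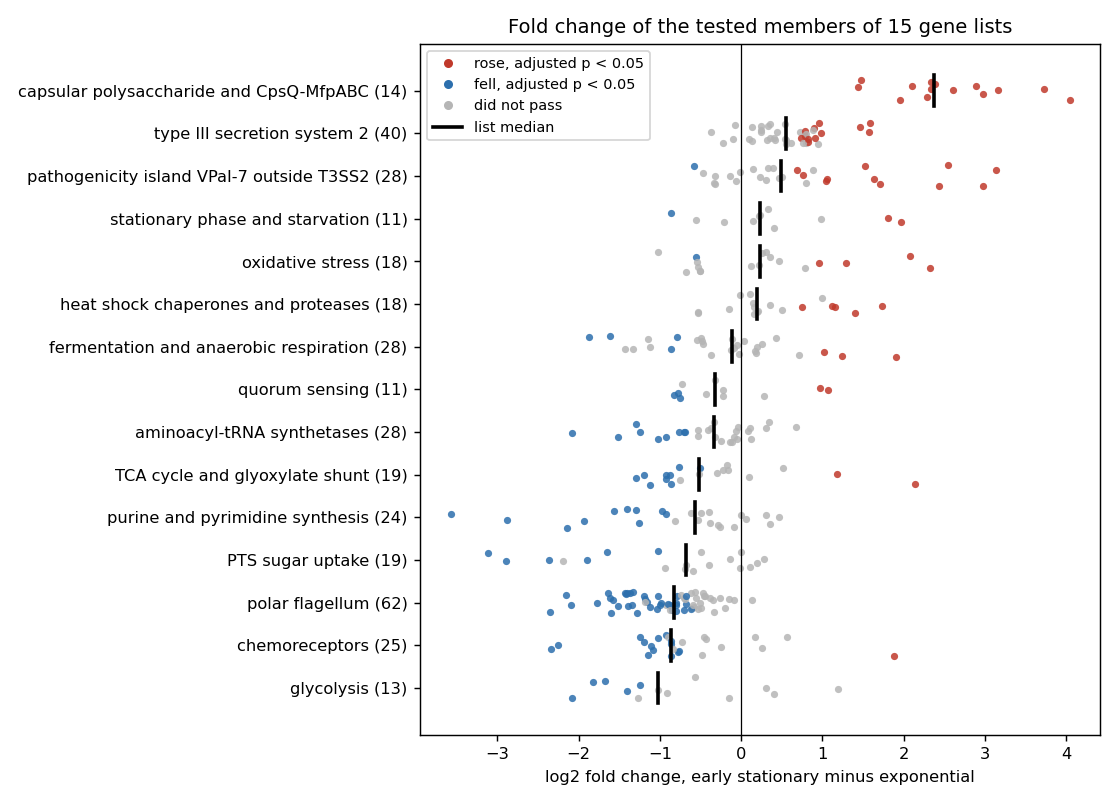
Log2 difference, early stationary minus exponential, of each tested gene (1 point per gene, coloured by whether it rose, fell or did not pass) in 15 lists, with the number tested in brackets and a black bar at the list median. All 14 genes of the list for capsular polysaccharide and CpsQ-MfpABC rose, with a median of 2.37, and 36 of 62 polar flagellum genes fell, with a median of -0.83.

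Of 62 tested polar flagellum genes 36 fell, 0 rose and 26 did not pass; 41 fell when adjusted over the list alone. The median difference was -0.83 and 61 of the 62 values were negative (camera adjusted p = 1.5e-10; adjusted p = 0.59 with an estimated correlation). With slide as a block and an estimated correlation the list passed (adjusted p = 0.008), the 1 list to do so. The slide medians were -0.94, -1.21 and -0.69, with an interaction adjusted p of 0.95, and no scaling changed the sign. The flgF gene VP0780 (chromosome 1, 814647 to 815396) fell from -0.27 ± 0.44 to -2.62 ± 0.23, its neighbour flgG (VP0781) fell by 2.16, flgJ (VP0784), above background on 1 early stationary array, by 2.09 and motY (VP2111) by 1.77. With normexp the difference of flgJ was 0.09 and motY was no longer called (-0.59). Of 25 tested chemoreceptor genes 14 fell, 1 rose and 10 did not pass (18 and 2 when adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.0034; adjusted p = 0.59 with an estimated correlation). VPA1651 (chromosome 2, 1765651 to 1767537) fell by 2.34 and was above background on 3 early stationary arrays, VPA1182 fell by 2.26, VP0421 fell by 1.25, and VPA0596 rose by 1.88. With normexp the falls of VPA1651 (0, adjusted p = 0.99), VPA1182 (-0.38) and VP0421 (-0.29) were no longer called, and with spike-in scaling the rise of VPA0596 was not (0.71). The slide medians were -0.55, -0.44 and -1.09, but the list's median was 0.1 with normexp, where its call was lost (adjusted p = 0.36). Of 31 tested lateral flagella genes 7 fell and 24 did not pass (5 when adjusted over the list alone; camera adjusted p = 0.45), and the lateral flagellin gene lafA (VPA1548) did not pass (-0.2, adjusted p = 0.71), except as lower with spike-in scaling (-1.37, adjusted p = 0.023).

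Of 24 tested genes of purine and pyrimidine synthesis 10 fell, 0 rose and 14 did not pass, and 10 fell when adjusted over the list alone. The median was -0.57 (camera adjusted p = 0.033; adjusted p = 0.89 with an estimated correlation). After pyrE the largest falls were those of guaA (VP0617, chromosome 1, 642937 to 644490) by 2.88, pyrF (VP2026) by 2.14 and carB (VP0471) by 1.93. With normexp guaA (-0.89) and carB (-0.49) were no longer called. The median was 0.17 on slide 1 and -1.06 and -1.52 on slides 2 and 3, with an interaction adjusted p of 3.2e-11. The camera call was lost when slide 2 or slide 3 was left out (adjusted p = 0.3 and 0.44), with the replicate number as a block (adjusted p = 0.073) and among genes above background on every array (adjusted p = 0.091).

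The central carbon lists did not pass in camera. In glycolysis 5 of 13 genes fell and 8 did not pass (5 when adjusted over the list alone; camera adjusted p = 0.27; adjusted p = 0.91 with an estimated correlation), with a median of -1.02. The falls included gpmM (VP2829) by 2.08, tpiA (VP0239) by 1.83, pykF (VP0356) by 1.68 and fbaA (VP2599) by 1.41. With normexp all 4 of these calls were lost, at -0.49, -0.82, -0.34 and -0.7. The glycolysis median was 0.4 on slide 1 and -2.0 and -1.64 on slides 2 and 3 (interaction adjusted p = 4.7e-06), and the slide 1 difference of tpiA was 0.39 and that of pykF 0.59. Of 19 sugar phosphotransferase genes 6 fell and 13 did not pass (6 when adjusted over the list alone; camera adjusted p = 0.12; adjusted p = 0.89 with an estimated correlation). The median was -0.68, with slide medians of -0.21, -0.58 and -1.57, and turned to 0.25 with normexp. The trehalose transporter gene VP0710 (chromosome 1, 743073 to 744497) fell from 0.15 ± 3.61 to -2.97 ± 0.95, with slide differences of 0.48, -5.19 and -5.73. The fructose transporter gene VPA1424, above background on 1 early stationary array, fell by 2.89, VPA1422 by 2.37 and the glucose transporter gene VP2046 by 1.9. With normexp none of these 4 was called, at -1.46, -0.73, -0.2 and -0.2. In the TCA cycle and glyoxylate shunt 9 of 19 genes fell, 2 rose and 8 did not pass (10 and 2 when adjusted over the list alone; camera adjusted p = 0.19; adjusted p = 0.89 with an estimated correlation; median -0.52). The rises were acnA (VP1646, chromosome 1, 1762626 to 1765217) by 2.14 and its neighbour prpC (VP1647) by 1.18, and gltA (VP0842) fell by 1.29 and sucD (VP0850) by 1.2. With spike-in scaling the rises were not called (0.97 and 0.01), and with normexp prpC (0.7) and sucD (-0.37) were not. Of 28 genes of fermentation and anaerobic respiration 3 rose, 4 fell and 21 did not pass (3 and 1 when adjusted over the list alone; camera adjusted p = 0.86; adjusted p = 0.95 with an estimated correlation). The genes torC (VP1161) and torA (VP1162) rose by 1.9 and 1.24, and napA (VPA1199) and nrfA (VP1929) fell by 1.87 and 1.61, with slide 1 differences of 0.7 and 0.21. The rises were not called with spike-in scaling (0.73 and 0.07), nor the falls with normexp (-0.97 and -0.06). The median of this list was -0.11 and turned to 0.05 with the array median and to 0.19 on slide 1.

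Of 28 tested aminoacyl-tRNA synthetase genes 9 fell and 19 did not pass, and 9 fell when adjusted over the list alone (median -0.33; camera adjusted p = 0.12; adjusted p = 0.59 with an estimated correlation). The falls included VP1291 for phenylalanyl-tRNA synthetase by 2.08, VP2548 for alanyl-tRNA synthetase by 1.52, VP2392 for a methionyl-tRNA synthetase-related protein by 1.29 and VP0021 for glycyl-tRNA synthetase by 1.24. Probes of VP0021 disagreed in direction. With normexp VP2392 and VP0021 turned positive, at 0.19 and 0.23, and VP1291 was no longer called (-0.22, adjusted p = 0.32). The slide medians were -0.12, -0.37 and -0.52. Of 51 ribosomal protein genes 1 rose, 3 fell and 47 did not pass (0 and 2 when adjusted over the list alone; camera adjusted p = 0.4), and of 13 translation factor genes 1 rose and 4 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.72).

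In the heat shock list 5 of 18 genes rose, 0 fell and 13 did not pass, and 5 rose when adjusted over the list alone (median 0.2; camera adjusted p = 0.035; adjusted p = 0.89 with an estimated correlation). The rises included a groES gene of chromosome 2 (VPA0286, 286375 to 286665) by 1.73, clpB (VP0561) by 1.4, hslU (VP0249) by 1.15 and ibpA (VP0018) by 1.12. The camera call was lost with quantile normalization (adjusted p = 0.096) and normexp (adjusted p = 0.64) and without exponential replicate 2 (adjusted p = 0.086), and the median was -0.97 with spike-in scaling, where none of these 4 genes was called and hslU and ibpA were -0.02 and -0.05. The slide medians were 0.06, 0.5 and 0.43. Of 18 oxidative stress genes 4 rose, 1 fell and 13 did not pass, with the same counts when adjusted over the list alone (median 0.23; camera adjusted p = 0.22; adjusted p = 0.89 with an estimated correlation). The superoxide dismutase gene sodC (VPA1514, chromosome 2, 1620670 to 1621185) rose from -2.06 ± 0.92 to 0.26 ± 0.27, katG (VPA0768) rose by 2.08, dps (VPA0563) by 1.29 and ahpF (VPA1684) by 0.96. The dps gene was above background on 3 of 8 exponential arrays. With spike-in scaling katG (0.91) and dps (0.12) were not called and ahpF was -0.21.

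The gene of the stationary phase sigma factor rpoS (VP2553, chromosome 1, 2697810 to 2698769) rose from -0.73 ± 0.35 to 0.62 ± 0.09, which is 2.54-fold (adjusted p = 1.7e-05), without overlap between the groups and by 1.29, 1.76 and 1.17 on the slides. With spike-in scaling its difference was 0.18 (adjusted p = 0.66), and with slide means as replicates its adjusted p was 0.074. In the list of stationary phase and starvation genes 2 of 11 rose, 1 fell and 8 did not pass, with the same counts when adjusted over the list alone (median 0.23; camera adjusted p = 0.19; adjusted p = 0.59 with an estimated correlation). The carbon starvation gene VP0540 rose by 1.97, the sigma-54 modulation protein gene VP2671 rose by 1.81 and the stringent starvation gene VP0445 fell by 0.86. With spike-in scaling the rises were not called (0.8 and 0.64), and with normexp VP0445 was 0.03. The medians of the oxidative stress and stationary phase lists were both -0.94 with spike-in scaling, and on slide 3 they were -0.31 and -0.22.

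In the quorum sensing list 2 of 11 genes rose, 3 fell and 6 did not pass, with the same counts when adjusted over the list alone (median -0.32; camera adjusted p = 0.72; adjusted p = 0.91 with an estimated correlation). The list's median was 0.07 with normexp. The sensor gene luxN (VP1968, chromosome 1, 2059377 to 2061929) rose by 1.07 and its neighbour luxM (VP1967) by 0.97, while luxQ (VPA1220) fell by 0.78 and hfq (VP2817) by 0.83. None of these 4 held under every scaling: with the spike-in controls luxN was -0.1 and luxM -0.21, with normexp luxQ was 0.07, and with the array median hfq was no longer called (-0.67, adjusted p = 0.14). The genes opaR (VP2516, -0.32, adjusted p = 0.62), aphA (VP2762, -0.73, adjusted p = 0.1) and luxO (VP2099, -0.22, adjusted p = 0.29) did not pass; aphA passed with slide as a block (-0.83, adjusted p = 0.0071) but not with slide means (adjusted p = 0.25). With spike-in scaling opaR (-1.49, adjusted p = 0.033), aphA (-1.9, adjusted p = 9.4e-05) and luxO (-1.39, adjusted p = 0.0025) passed as lower, against a median of -1.32 for all genes. Probes of opaR and of aphA disagreed in direction, and the annotation calls the product of the aphA locus a conserved hypothetical protein. Of the other fixed regulators crp (VP2793, chromosome 1, 2956816 to 2957448) fell by 1.32 (adjusted p = 0.0078), with slide differences of 0.24, -2.41 and -2.21. The genes hns (VP1133, -0.01, adjusted p = 0.99), fis (VP2885, 0.1, adjusted p = 0.72) and fur (VP0833, -0.83, adjusted p = 0.065) did not pass, although fur did with slide as a block (-0.74, adjusted p = 0.03), a call lost with slide means (adjusted p = 0.38). With spike-in scaling fis (-1.07, adjusted p = 0.029) and fur (-2.0, adjusted p = 0.0016) passed as lower. Of 96 tested genes named by the rule 84 were called, 78 of them in the same direction on all 3 slides. The 6 exceptions, positive on slide 1 and negative on slides 2 and 3, were crp, tpiA, pykF, napA, nrfA and VP0710. With slide means as replicates 47 of the 84 were called.

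The other lists did not pass in camera. Of 54 amino acid synthesis genes 3 rose and 6 fell (3 and 3 when adjusted over the list alone), of 8 ATP synthase genes 1 fell, and of 4 RNA polymerase core genes none passed. Of 13 genes for compatible solutes 1 fell, of 30 type VI secretion system 1 genes 3 rose and 1 fell (1 and 0 when adjusted over the list alone), and of 17 type IV pilus genes 1 rose (0 when adjusted over the list alone). Of 9 vibrioferrin genes 2 fell (1 when adjusted over the list alone), of 32 iron and heme uptake genes 1 rose and 2 fell, and of 5 chitin degradation genes 2 fell. Of 29 peptide transport genes 1 rose and 6 fell (1 and 5 when adjusted over the list alone), of 24 genes for GGDEF and EAL domain proteins 2 rose and 4 fell, and of 67 superintegron genes 3 rose and 10 fell (2 and 8 when adjusted over the list alone). Of 5 tested genes of phage f237 3 rose. Where no second count is given the count adjusted over the list alone was the same. The medians of these lists, and those of the ribosomal protein, translation factor, type III secretion system 1 and lateral flagella lists, changed sign under at least 1 of the other scalings, except that of the ATP synthase genes. Their camera adjusted p lay between 0.061, for phage f237, and 0.97. The type VI secretion system 2 had 2 tested genes, of which 1 rose (2 when adjusted over the list alone), and the array has no ribosomal RNA probes, so neither list was tested. Camera compares a list with the other tested genes, and its direction was upward while the median was negative for amino acid synthesis, fermentation, peptide transport and GGDEF and EAL domain proteins; for compatible solutes the median was 0.04, the mean -0.18 and camera's direction downward.

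A further comparison asked whether the growth phases differ in how signal is spread over the genome, using values within an array that do not depend on its scaling factor. The mean log2 value of chromosome 2 genes minus that of chromosome 1 genes was -1.24 ± 0.27 in exponential and -1.02 ± 0.03 in early stationary phase (SD, n = 8 arrays each; exact permutation p = 0.027, adjusted p = 0.027). The difference of 0.21 was 0.05, 0.6 and 0.13 on slides 1, 2 and 3. It no longer passed with slide means, here without a block (exact p = 0.1), without slide 1 (0.31, exact p = 0.063), without slide 2 (0.08, exact p = 0.22) or with the median over genes (exact p = 0.12). The slope of the log2 value from origin to terminus on chromosome 1 was -1.7 ± 0.41 in exponential and -1.26 ± 0.07 in early stationary phase (exact permutation p = 0.0053, adjusted p = 0.008). On the slides its difference was -0.03, 1.08 and 0.45, so it was close to 0 on slide 1, and it did not pass without slide 2 (0.2, exact p = 0.11) or with slide means (0.5, exact p = 0.2). On chromosome 2 the slope was -0.59 ± 0.24 and -0.11 ± 0.05 (exact permutation p = 0.00016, the smallest these splits can give, adjusted p = 0.00048), with slide differences of 0.31, 0.81 and 0.47. This difference was 0.17 with normexp and 0.28 among genes above background on every array. These tests permute arrays as if independent, and with slide means no exact p can be under 0.1. Within a slide no exact permutation test could give a p under 0.1.

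**Figure D3:**
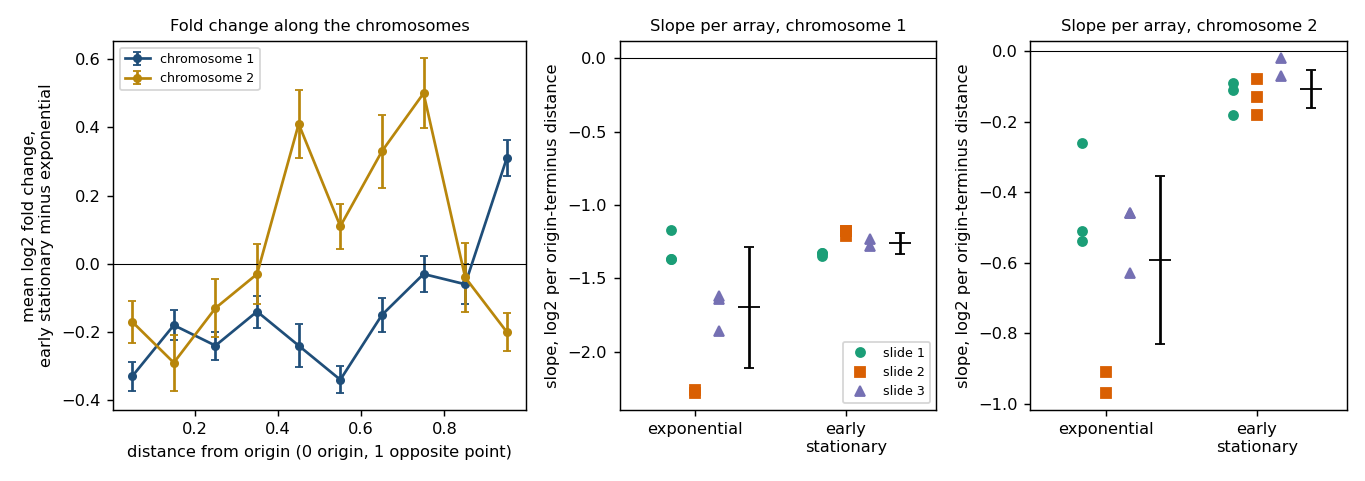
Mean log2 difference, early stationary minus exponential, of tested genes by distance from the replication origin (0 at the origin, 1 at the opposite point; bars are standard errors over genes), and the slope of the log2 value on that distance for each array by growth phase, with the slide as colour and shape and bars for the mean ± SD of 8 arrays. On chromosome 2 all 8 exponential slopes, from -0.97 to -0.26, were below all early stationary slopes, from -0.18 to -0.02.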

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

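The tests of why the exponential arrays of slide 1 differ were chosen only after the result was seen; the search for values far from the others of their group was planned.

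Among the 96 tested genes named by the rule and the values per array, 206 groups of 8 arrays were searched for a highest or lowest value that lay far from the nearest other one. Such a gap was found in 4 groups, where chance alone gives about 1 in 20, or 10.3, if the 8 values of a group are independent; values of a slide lay together, so that number is a rough guide only. VP2829 (gpmM) was -3.47 on early stationary replicate 8, and its nearest other value was -2.87. VPA1199 (napA) was -2.67 on the same array against -1.24 for the nearest. VP0421, a chemoreceptor gene, was 0.18 on exponential replicate 6 against -0.63, and VPA1220 (luxQ) was -3.9 on early stationary replicate 7 against -3.04. All 4 values came from slide 3. No explanation was tested for them.

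The exponential arrays of slide 1 differed from those of slides 2 and 3. Within exponential phase 1032 genes passed for this difference, 597 of them higher on slide 1, and within early stationary phase 1523 genes did. The growth phase difference itself was not the same on slide 1 for 869 genes in a test of the interaction. These counts take the arrays of a slide as independent, so they do not measure a spread among slides. The median absolute log2 difference of the called genes was 0.72 on slide 1, 1.35 on slide 2 and 1.47 on slide 3.

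A slide effect shared by both phases would give each gene a like difference in both, but the differences had an SD over genes of 1.09 in exponential and 0.75 in early stationary phase, a ratio of 0.69, and correlated across genes with r of 0.34, so a shared effect alone is argued against. A single mislabelled array is also argued against, since 0 of the 3 exponential arrays of slide 1 resembled the early stationary arrays of their slide more than each other. The margin was small, with a difference in r of -0.03 for the closest array. An error common to all 3 could not be seen this way, since each was compared with the other exponential arrays of its slide. A candidate explanation is that these cultures were further along towards early stationary phase: their difference from the exponential arrays of slide 2 correlated across genes with the phase difference of slide 3 (r of 0.47), and that from slide 3 with the phase difference of slide 2 (r of 0.24). The same comparisons of early stationary arrays gave r of 0 and -0.23, of which the second was nearly as large as 0.24 with the opposite sign, so the support from the lower value is weak. Genes are not independent replicates, this was found and tested on the same data, and a difference in handling between the slides stays open.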

How the results depend on the processing

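Removing exponential replicate 2, 6 or 8, slide means as replicates, and the set test with both slide block and estimated correlation were chosen after seeing the data. The 7 results that answer a comparison changed little under quantile normalization, the series table, slide block, replicate block (1349 genes, 788 of them 2-fold, and 6 lists), eBayes with a trend, and the rank of the locus number, where these apply. There the values per array kept their direction and side of the threshold. Counts of genes and lists stayed within 1.5 times the main count, and the share of higher calls lay between 38.6 and 47.6%. The majority at 2-fold still turned to higher under quantile normalization and in the series table. Of the 8 lists that passed in each of these 2 settings, 6 were among the main 7. With the array median the share of higher calls was 54%. With spike-in scaling 2940 genes passed, 2746 of them by at least 2-fold, and the share was 3.37%. With normexp 807 genes, 173 of them 2-fold, and 14 lists passed, with a share of 69.0%. With a filter for genes above background on every array, which tests fewer genes, 775 genes, 384 of them 2-fold, and 3 lists passed. Camera with an estimated correlation gave 0 lists, 1 with slide block as well, and fry gave 13. Without slide 1 1236 genes changed at least 2-fold and 12 lists passed; without slide 2 687 genes passed. Within slide 2 2463 genes passed, 1461 of them 2-fold, with a share of 49.4%, and within slide 3 1249 genes were 2-fold. With slide means and slide as a block together 239 genes passed, all of them 2-fold, with a share of 67.8%; for single genes slide means below include that block, and for the per-array values they do not. Without the 3 exponential arrays 2, 6 and 8 the share was 49.5% and the chromosome difference 0.36 (exact p = 0.00078), against 0.21 with all arrays. Without 1 of these arrays the ranges were 1210 to 1350 genes, 731 to 842 genes at 2-fold, shares of 38.9 to 42.4%, 7 lists, chromosome differences of 0.24 to 0.26 and slopes of 0.44 to 0.51 and 0.51 to 0.53. Of the 7 lists, those for T3SS2, the rest of VPaI-7, the polar flagellum and the capsule kept their calls in the alternatives run for lists, which leave out the array median, spike-in scaling and single slides, except with an estimated correlation (where the polar flagellum passed with slide block as well); too few capsule genes were left to test under the filter for every array. With spike-in scaling the medians of T3SS2 and the rest of VPaI-7 were negative (-0.62 and -0.68). Chemoreceptors also lost theirs with normexp and that filter (adjusted p = 0.36 and 0.076). Nucleotide synthesis lost its call with that filter (0.091), without slide 2 or 3 (0.3 and 0.44) and with replicate block (0.073). Heat shock lost its call under 9 further alternatives, with adjusted p from 0.054 without slide 3 to 0.64 with normexp.

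The chromosome difference missed the threshold with no filter (0.2, exact p = 0.082), with the median over genes (0.21, exact p = 0.12), without slide 1 (0.31, exact p = 0.063), without slide 2 (0.08, exact p = 0.22), with slide means (0.26, exact p = 0.1) and within slides 1, 2 and 3 (0.05, 0.6 and 0.13, where no exact p can be under 0.1). The chromosome 1 slope difference was reversed within slide 1 (-0.03) and missed the threshold within slides 2 and 3 (1.08 and 0.45), without slide 2 (0.2, exact p = 0.11) and with slide means (0.5, exact p = 0.2). The chromosome 2 slope difference missed it within the slides (0.31, 0.81 and 0.47) and with slide means (0.53, exact p = 0.1), where the number of samples cannot give a p under 0.1. It was past the threshold but smaller with normexp (0.17) and with the filter for every array (0.28), against 0.49.

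Of the 84 called named genes the alternatives lost 4 with the array median, 6 with the series table, 0 with slide block and replicate block, 6 with the brightest probe, 16 with spike-in scaling, 22 with normexp and 37 with slide means, and a further 7, 5 and 1 of them were reversed with spike-in scaling, normexp and the brightest probe. Of the 12 named genes not called, 3 were gained with the array median, 7 with spike-in scaling (as lower), 4 with slide block, 3 with replicate block, and 1 each with normexp, the brightest probe and the series table, besides reversed ones. Reversals of genes, called or not, were these. With the array median VP1133 was 0.16 and VP0819 0.05. With spike-in scaling VP0820 was -0.81, VPA1332 -0.37, VPA1348 -0.45, VPA1314 -0.14, VP2885 -1.07, VP0249 -0.02, VP0018 -0.05, VPA1684 -0.21, VPA1362 -0.19, VP1968 -0.1 and VP1967 -0.21. With normexp VP2516 was 0.3, VP2762 0.27, VP1133 0.37, VP0819 0.31, VPA0226 0.09, VP2885 -0.04, VPA1548 0.37, VP2392 0.19, VP0021 0.23, VP0445 0.03, VP0784 0.09 and VPA1220 0.07. With the brightest probe VP2762 was 0.03, VP1133 0.16, VP0819 0.46, VPA1548 0.02 and VP0021 0.05. With the series table VP1133 was 0.18 and VP0819 0.23, and VP1133 was 0.03 with slide block and 0.05 with slide means. For the lost and reversed genes, the moved shares and the lists the cause was not tested. With normexp the offset by itself shrinks and shifts the differences of dim genes, as said above. Whether replicate numbers pair the phases could not be decided. After the group means were removed, arrays of the same number correlated across genes with a mean r of 0.17. The mean r was 0.14 for other numbers of the same slide and -0.08 for other slides. Arrays of the same number share a slide, except for replicate 6, so these means cannot tell pairing from slide. Replicate 6, on slide 3 in exponential and slide 2 in early stationary phase, had r of 0.3, but it is a single pair. Replicates 4 and 5, with both arrays on slide 2, had r of -0.03 and -0.05. Signal limits the calls on dim genes: 51 called genes were above background on no array of a group, so their folds are bounds only.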

Other observations

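The tests of the spike-in signal and of gene dosage, the search of product words and the runs of neighbouring genes were chosen only after results were seen; the tests of other splits and of signal-dependent compression were not.

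Other splits of the 16 arrays into 8 and 8 were compared with the real one. Among 100 splits, 1, the real one, gave as many as 1324 called genes, and the highest other gave 527; for genes at 2-fold it was again 1 of 100, with 780 against 363. Arrays of a slide were not independent, so these splits do not exclude chance for either count. The other splits also mix both phases on each side, so the phase difference adds to their spread and lowers their counts. The splits move single arrays between slides, so they do not test chance among slides, for which 3 slides are too few; with slide means as replicates and slide as a block 239 genes passed. Of the 99 other splits 97 gave no called gene. The split with 527 genes put all 6 arrays of slide 1, with early stationary replicates 4 and 8, on one side, so it follows the slide; with slide as a block the real count was 1771.

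The gene signal relative to the spike-in controls was lower in early stationary phase. The 75th percentile of the gene signal minus the spike-in mean was -3.94 ± 0.47 on exponential and -5.11 ± 0.75 on early stationary arrays (log2, SD, n = 8 each; exact permutation p = 0.0026), a difference of -1.17. Within slides 1, 2 and 3 it was -1.49, -1.4 and -0.45. A dimmer hybridisation or scan would lower the spike-in mean too, but this mean was higher in early stationary phase by 0.16, 0.19 and 0.47 on the slides, which argues against that explanation. A lower share of messenger RNA in total RNA may explain it, with -0.45 as the within-slide difference nearest to 0; it cannot be told apart from a difference in the spike-in amount per RNA, which the sources do not give.

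The growth phase difference rose with distance from the origin. Signal-dependent compression of the array values is argued against, since the slopes after removal of a smooth trend on signal were 0.54 (SE 0.05) on chromosome 1 and 0.51 (SE 0.1) on chromosome 2. Higher gene dosage near the origin in exponential cultures is a candidate explanation for chromosome 1. Both arms there had positive slopes, 0.49 and 0.37 (SE 0.08 each). It stays open, since slide 1 had a slope of -0.03 (SE 0.05) and the rise was not steady. The mean difference was -0.33 around a distance of 0.05, -0.34 around 0.55 and 0.31 around 0.95. The SEs here count genes as independent, although neighbouring genes often changed together. On chromosome 2, of 5 equal parts the one opposite the origin had a mean of -0.11 and the middle one a mean of 0.26 (difference -0.38, SE 0.09). The middle part holds VPaI-7 and the capsular polysaccharide genes near VPA1410, where many genes rose. The comparison therefore cannot decide on dosage there. The arms of chromosome 2 had slopes of 0.19 (SE 0.13) and 1.0 (SE 0.18). Among genes that did not pass as changed the slopes of chromosomes 1 and 2 were 0.13 (SE 0.04) and 0.13 (SE 0.06). Such genes mostly have small differences, so smaller slopes follow from the choice of genes and do not bear on dosage.

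A search of 214 words in the product names, with 428 tests, found 8 that passed among the called genes (Fisher's exact test, adjusted over the tests). Of 13 tested genes with acyl-CoA in their product 11 rose, where 1.6 were expected (adjusted p = 2.4e-06), and of 6 with enoyl-CoA all 6 rose (adjusted p = 0.00036). Hydratase (7 of 11) and cytochrome (15 of 42; both adjusted p = 0.0053) also passed among the rises. In the other direction 6 cytochrome, 1 acyl-CoA, 1 hydratase and 0 enoyl-CoA genes fell. Flagellar (28 of 54), polar (21 of 37), chemotaxis (19 of 38) and methyl-accepting (12 of 21) passed among the falls. The words overlap in their genes, and the test counts neighbouring genes that change together as independent: 8 of the 11 acyl-CoA genes and all 6 enoyl-CoA genes lie in the runs VPA0616 to VPA0626 and VPA1119 to VPA1129.

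Neighbouring tested genes often changed together. There were 31 runs of at least 5 neighbouring genes called in the same direction, 18 upward and 13 downward. In a smaller set of shuffled orders their number had a median of 1 and was at most 5. The longest run held 12 genes, against at most 8 in 1000 shuffled orders: VPA1143 to VPA1154 (chromosome 2, 1206611 to 1218447), with a median rise of 2.05. The genes that bound the runs named here were chosen after their values were seen. Other upward runs were VPA0616 to VPA0626 (620229 to 632291, median 2.79), VPA1119 to VPA1129 (1181352 to 1194659, median 2.5), VPA1403 to VPA1413 (1475072 to 1487072, median 2.39), which holds 10 capsular polysaccharide list members, VPA0535 to VPA0543 (537839 to 546749, median 2.1) and, on chromosome 1, VP2417 to VP2424 (2535760 to 2542625, median 2.65), which holds the fimbrial gene VP2423. Downward runs included VPA1615 to VPA1623 (1713346 to 1727876, median -1.63), which holds the maltodextrin phosphorylase gene, VP1774 to VP1782 (1890796 to 1899016, median -1.43) and VPA0801 to VPA0805 (828140 to 835238, median -2.13). Each of these runs had a median of the same sign on all 3 slides. The runs were picked from calls on the same arrays, so this largely follows from the choice and is not separate support.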
